A study of Mus musculus with 67 samples.

How the data were processed

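The series holds 67 samples of neural stem cell cultures from the mouse ventricular-subventricular zone (V-SVZ), the germinal layer along the lateral ventricles of the brain. Of these, 20 are RNA sequencing libraries, in 10 groups of 2. The other 47 are CUT&RUN samples, which map histone marks on chromatin, and were not analysed here. Each RNA library was placed in its group by its title, and the replicate number was taken from the same title. Nothing in the labels says that the 2 libraries of a group came from separate animals or separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels, the libraries were poly(A)-selected and strand-specific, from total RNA of cells grown with EGF and FGF (20 ng/mL each), serum (5%) and extract of bovine pituitary (35 µg/mL), derived from C57BL/6 mice at postnatal day 7. The run names in the labels differ between experiments, and the Smo, Mll1 and washout libraries carry 2 run names each. Every comparison was made within 1 experiment, which by itself does not show that its groups shared a run. The run names of the MM-401 control libraries mention ethanol, whereas their treatment label gives DMSO, and the treatment label was followed. A run name of Smo F/F replicate 2 says Rep1, as does that of replicate 1, whereas the title says Rep2, so whether these libraries are separate replicates rests on the title.

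Each deposited file lists estimated counts for 122968 mouse transcripts, with their length and effective length. Per the file headers, the values are estimated counts per transcript, which need not be whole because reads that match several transcripts are divided among them. The submitters' processing notes name kallisto 0.43.0 and sleuth 0.29.0, the genome builds GRCm38.p5 and mm10, and Bowtie2 2.2.6 and MACS2. They give no role for each, and how the reads were trimmed or which transcript annotation was used is not given in the sources used here. The deposited estimated counts were not normalized between libraries, and their totals ran from 39036931 to 84837069 per library.

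The files carry Ensembl transcript IDs alone and do not pair them with gene names. The reference tables used here pair gene IDs with symbols and held 0 lines with an Ensembl transcript ID. Transcripts could therefore not be summed per gene. The 21 gene lists fixed before the data were examined (regional regulators, Hedgehog pathway, MLL complex subunits, cell types, stress and signalling targets) and the checks of Smo and of Mll1 (Kmt2a) in the libraries that should lack them could not be made. All results are for transcripts in place of genes, and no genome coordinates are given.

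Estimated counts were rounded to whole numbers. Transcripts were kept with filterByExpr of edgeR (count minimum 10, by group), which left 63900 transcripts that held 99.9% of the counts. Libraries were scaled with TMM. Differences were tested with the edgeR quasi-likelihood test (robust), two-sided, in 1 fit over all 20 libraries with group as the only term and 10 residual degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method and a transcript was called changed at an adjusted p below 0.05. The common biological coefficient of variation was 49.1%. Fold changes are log2 values. Each standard error is the log2 fold change divided by the z-score of its p-value. Levels are CPM values (counts scaled to library size) with TMM scaling. Where every library of a group held 0 after rounding, a fold is given as a bound against 3 counts in each library, and such bounds cover counting error only.

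The 5 comparisons were ventral against dorsal cells, Smo F/F against control, Mll1 F/F against control, MM-401 against control, and washout of MM-401 against its control. The difference between the washout and treatment effects, and that between the Mll1 F/F and MM-401 effects, were tested as contrasts in the same fit. Transcripts called in the ventral against dorsal comparison with a fold of at least 2 formed the ventral-enriched set (691) and the dorsal-enriched set (721). Each set was tested in the other 4 comparisons with cameraPR of limma on signed z-scores, with a preset correlation of 0.01, adjusted over 8 tests. The 4 libraries that define the sets enter none of those comparisons. The same test with a correlation estimated from the residuals (camera on log2 CPM) is given beside it. Overlaps of called transcripts were tested with a one-sided Fisher's exact test, and transcripts are not independent replicates. Sets of transcripts changed at least 2-fold by MM-401 were added after the data were seen, and adjusted over 6 tests, as were the differences of the region sets between effects, adjusted over 4.

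The transcripts named were chosen by a rule written before the data were examined. Among called transcripts with an average log2 CPM of at least 1, and with both libraries of one group above both of the other, the 12 that rose most and the 12 that fell most were ranked by log2 fold change. Because IDs without gene names say little, at most the first 2 in each direction are printed for each comparison.

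The estimated counts of 2728 tested transcripts were whole, within 0.01, in all 20 libraries, so that no fractional division of reads showed. Whether each of their reads matched 1 transcript only was not tested. Alternatives planned in advance were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, an effective length offset, a fit on only the libraries of a comparison, the replicate number as a block, each library left out in turn, limma on log2(TPM + 1) and log2(TPM + 0.1), other definitions of the region sets, and an estimated correlation. TPM was computed from the estimated counts and effective lengths. Restricting the tests to whole-count transcripts or to transcripts with an average log2 CPM of at least 1 was chosen after seeing the data. So were MM-401 sets chosen with the libraries of 1 replicate number and measured in those of the other, and overlaps set against 1000 permutations of the calls within 50 bins of abundance.

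The pipeline was tested on simulated counts with the means and library sizes of the real libraries, over 61455 transcripts for each comparison. Of 100 transcripts changed 4-fold, 29 were recovered for ventral against dorsal, 26 for Smo F/F, 24 for Mll1 F/F, 20 for MM-401 and 20 for the washout, and among the seeded transcripts with an average log2 CPM of at least 1 the share was between 50.0% and 76.5%. Of 100 changed 2-fold, 6, 4, 10, 7 and 6 were recovered in the same order, with at most 2 false calls. In a simulation of the Smo F/F comparison over 63900 transcripts, a set of 500 shifted by 0.2 had a mean log2 fold change of 0.19 and an unshifted set one of -0.0039. Simulated transcripts were drawn independently, so this does not test shifts of real sets, whose members vary together. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8), and plots used Python 3.11.15 with matplotlib 3.10.9.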

Results

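RNA was sequenced from neural stem cell cultures of the mouse V-SVZ to ask how the regional (positional) identity of these cells is kept. The 10 groups were untreated dorsal cells, untreated ventral cells, and 8 groups of ventral cells in 4 experiments, each with 2 libraries per group. In the Smo and Mll1 experiments, cells carried UBC-CreER, a Cre recombinase that is switched on by 4-hydroxytamoxifen, with floxed alleles of Smo, the membrane protein that passes on the Hedgehog signal, or of Mll1 (Kmt2a), a histone H3 lysine 4 methyltransferase. The F/F cells and their controls, whose run names mark them as heterozygous, received 100 nM 4-hydroxytamoxifen in 1% ethanol for 4 days (2 passages). In the other experiments cells received 25 µM MM-401, an inhibitor of the binding of MLL1 to its partner WDR5, in 1% DMSO for 10 days, or 1% DMSO alone, and were collected then or after a further 10 days without either. Library totals ran from 39036931 to 84837069 estimated counts, with the 4 libraries of the MM-401 experiment between 39036931 and 42322960.

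Replicate libraries differed by more than sampling noise in every group, with a chi-square per degree of freedom from 13.2 in the MM-401 controls to 41.9 in the Mll1 controls. The 2 MM-401 libraries stood apart from all others on the first principal component, at 265 and 242, while the other 18 lay between -122 and 54.5. In the Mll1 experiment the replicates differed more than the genotypes on that component. The replicate 1 libraries lay at 54.5 (F/F) and 46.6 (control), and the replicate 2 libraries lay at -16.2 and -32.2. The files do not pair transcripts with gene names, so transcripts are described in sets and a few are given by ID. Depletion of Smo or Mll1 RNA in the F/F libraries was therefore not checked here.

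**Figure D1:**
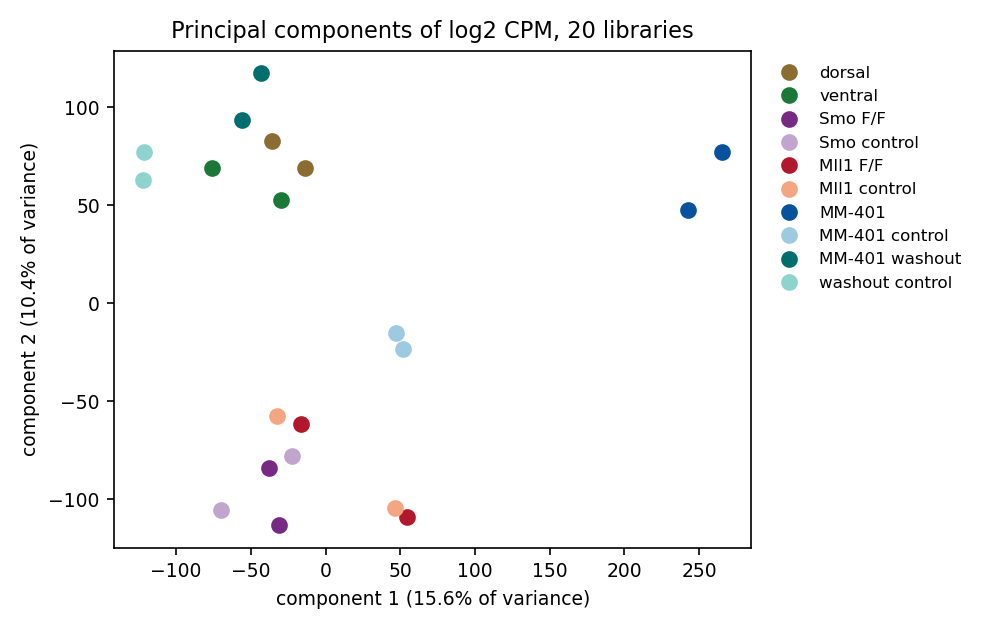
Each point is 1 of the 20 libraries, coloured by group, on the first (horizontal, 15.6% of the variance) and second (vertical, 10.4%) principal components of log2 CPM over 63900 transcripts, in arbitrary units. The MM-401 libraries lie at 265 and 242 on the horizontal axis and no other library lies above 54.5.

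The first comparison asked which transcripts distinguish ventral from dorsal cells in culture. Of 63900 transcripts tested, 2372 (3.71%) differed, with 1036 higher and 1336 lower in ventral cells. Differences were often large, since 691 were at least 2-fold higher and 721 at least 2-fold lower, and the median absolute log2 fold change of those called was 1.22. ENSMUST00000155282 was at 11.3 and 13.2 CPM in the ventral libraries and 0 in both dorsal libraries, at least 168-fold higher. ENSMUST00000184867 ranked first among the transcripts that rose, but was at 0.101 CPM in one ventral library, 33.4 CPM in the other and 0 in both dorsal libraries (adjusted p = 0.0347, edgeR). ENSMUST00000099497 was lower in ventral cells, at 0.338 ± 0.208 CPM against 17.9 ± 10.3 CPM (SD, n = 2 each), a log2 fold change of -5.72 ± 1.15 (SE, adjusted p = 0.000363, edgeR). ENSMUST00000182603 was at 0 and 0.0191 CPM in the ventral libraries and at 0.598 and 2.48 CPM in the dorsal libraries (adjusted p = 0.00386, edgeR). All 4 of these transcripts had estimated counts that were not whole, so part of each value depends on how reads were divided between transcripts.

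The number of transcripts that differed between the regions was 5143 with the DESeq2 Wald test and 0 in a fit of these 4 libraries alone with edgeR, where 2 residual degrees of freedom remain and 9625 transcripts had an unadjusted p below 0.05 in the fit of all libraries. It was 968 without dorsal replicate 1, 1426 without ventral replicate 1 and 1409 without ventral replicate 2. ENSMUST00000155282 missed the threshold without any 1 of the 4 libraries (adjusted p from 0.0754 to 0.207, edgeR) and with a replicate block (adjusted p = 0.0809), and ENSMUST00000184867 missed it without either dorsal library or ventral replicate 2 (adjusted p from 0.128 to 0.202, edgeR).

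**Figure D2:**
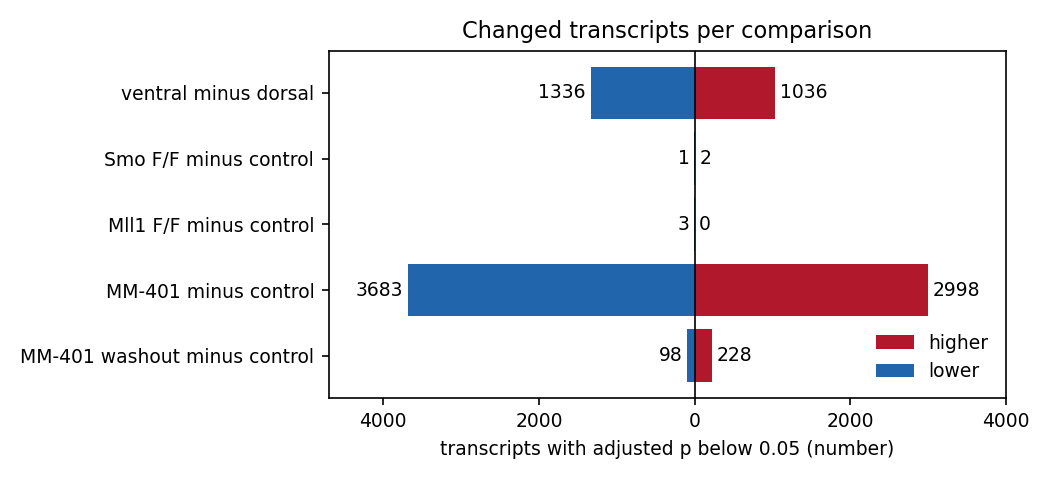
Bars give the number of transcripts higher (right, red) and lower (left, blue) in each of the 5 comparisons at an adjusted p below 0.05 (edgeR), on a linear axis from 0 in both directions. MM-401 changed 2998 upward and 3683 downward, against 2 and 1 for Smo F/F and 0 and 3 for Mll1 F/F.

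The Smo F/F comparison asked how ventral cells change on loss of Smo. As a set, the ventral-enriched transcripts were lower in Smo F/F cells and the dorsal-enriched transcripts were higher, but neither set passed the threshold with an estimated correlation (adjusted p = 0.055 for the ventral-enriched and adjusted p = 0.0634 for the dorsal-enriched set). Of the 691 ventral-enriched transcripts, 27.8% had a log2 fold change above 0, and their mean was -0.18 (adjusted p = 2.86e-08, cameraPR). Of the 721 dorsal-enriched transcripts, 74.3% were above 0, with a mean of 0.21 (adjusted p = 5.66e-12, cameraPR). These shifts were small beside the regional differences that define the sets. Against the mean of their controls, the 2 Smo F/F libraries stood at -0.21 and -0.14 for the ventral-enriched set and at 0.21 and 0.20 for the dorsal-enriched set, while the controls lay at 0.016 and -0.016 and at 0.013 and -0.013.

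Few single transcripts were called. Only 3 of 63900 passed the threshold in Smo F/F cells, with 2 higher and 1 lower, and no member of either region set did so by itself. ENSMUST00000001812 fell from 116 ± 7.01 CPM to 29.0 ± 10.1 CPM (SD, n = 2 each), a log2 fold change of -2.0 ± 0.36 (SE, adjusted p = 0.00178, edgeR). ENSMUST00000073551 rose from 8.28 ± 0.778 CPM to 17.4 ± 0.0492 CPM (SD, n = 2 each), a log2 fold change of 1.07 ± 0.20 (SE, adjusted p = 0.00178, edgeR). ENSMUST00000197402 was at 0.68 and 1.16 CPM in Smo F/F cells and 0 in both controls, at least 22.7-fold higher (adjusted p = 0.00741, edgeR), and missed the threshold without Smo control replicate 2 (adjusted p = 0.0972). The estimated counts of these 3 transcripts were not whole. An unadjusted p below 0.05 was found for 1362 transcripts (2.13%), fewer than the 5% that chance alone would give. The p-values of this comparison thus ran large, and the low count does not show that few transcripts changed. The DESeq2 Wald test called 38 (20 higher and 18 lower). With a replicate block, and in a fit of these 4 libraries alone, the count was 0, and the 3 transcripts had an adjusted p from 0.369 to 0.401 with the block. Without Smo control replicate 1, Smo F/F replicate 1 or Smo F/F replicate 2 the count was 19, 14 and 7.

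The Mll1 F/F comparison asked the same of Mll1. Only 3 transcripts were called, and all of them fell. ENSMUST00000094463 fell from 31.6 ± 0.21 CPM to 9.39 ± 1.42 CPM (SD, n = 2 each), a log2 fold change of -1.75 ± 0.30 (SE, adjusted p = 0.000285, edgeR). ENSMUST00000217212 was at 0.061 and 0 CPM in Mll1 F/F cells and at 1.19 and 2.26 CPM in controls (adjusted p = 0.0411, edgeR). The third was below the abundance minimum of the naming rule. The estimated counts of the named transcripts were not whole. The dorsal-enriched set was higher, with a mean of 0.16 and 62.0% of its transcripts above 0 (adjusted p = 3e-05, cameraPR, but adjusted p = 0.269 with an estimated correlation). The ventral-enriched set had a mean of 0.055 (adjusted p = 0.181, cameraPR). The Mll1 F/F libraries stood at 0.20 and 0.090 for the dorsal-enriched set, and the controls at 0.079 and -0.079. If libraries of the same replicate number belong together, F/F minus control was 0.12 and 0.17 for the dorsal-enriched set and 0.052 and 0.055 for the ventral-enriched set. With a replicate block the call of each set was unchanged (adjusted p = 1.92e-05 and adjusted p = 0.0786). For the ventral-enriched set replicate 1 lay below replicate 2 in both groups (-0.018 and 0.125 in F/F, -0.07 and 0.07 in controls). If the numbers pair the libraries, leaving out a single Mll1 library breaks a pair and mixes this difference into the mean.

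The call of the dorsal-enriched set in Mll1 F/F cells was lost without Mll1 control replicate 2 (mean 0.12, adjusted p = 0.718) and over whole-count transcripts alone (mean 0.070, adjusted p = 0.123), and its mean was 0.077 without Mll1 F/F replicate 1 and 0.27 without Mll1 control replicate 1. The ventral-enriched set passed without Mll1 F/F replicate 1 (mean 0.095, adjusted p = 0.0163) or ventral replicate 1 (mean 0.076, adjusted p = 0.0296), but its direction was not stable. Its mean was -0.055 without Mll1 F/F replicate 2, -0.028 without dorsal replicate 2, -0.017 without ventral replicate 2, -0.0033 over whole-count transcripts and 0.18 without Mll1 control replicate 2, and it did not pass in any of these. The number of changed transcripts was 184 with the DESeq2 Wald test (84 higher and 100 lower), 1 with a replicate block (ENSMUST00000217212 missed the threshold, adjusted p = 0.742), 0 in a fit of these 4 libraries, and 28, 37, 5 and 32 without Mll1 control replicate 1, Mll1 control replicate 2, Mll1 F/F replicate 1 and Mll1 F/F replicate 2. An unadjusted p below 0.05 was found for 2399 transcripts (3.75%), against 5% by chance, so here too the low count does not show that few transcripts changed.

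**Figure D3:**
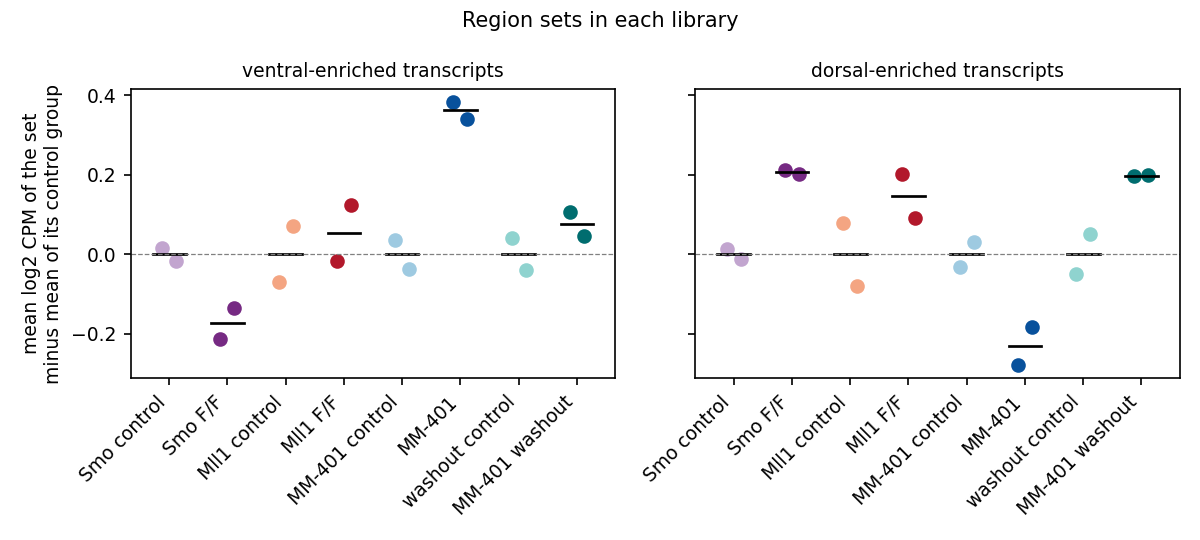
Points are single libraries and bars are means of 2, showing the mean log2 CPM of the 691 ventral-enriched (left) and 721 dorsal-enriched (right) transcripts, minus the mean of that experiment's controls, for the 8 ventral groups in 4 experiments. Smo F/F libraries lie at -0.21 and -0.14 on the left and 0.21 and 0.20 on the right, and MM-401 libraries lie at 0.38 and 0.34 on the left and -0.28 and -0.18 on the right.

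MM-401 had a far wider effect on ventral cells. It changed 6681 of 63900 transcripts (10.5%), of which 2998 rose and 3683 fell, and 1622 rose and 2371 fell at least 2-fold. Whether the controls received DMSO, as labelled, or ethanol, as in their run names, is uncertain, so a vehicle difference is not excluded. The median absolute log2 fold change of those called was 1.21, whereas the median over all transcripts was -0.058. With DESeq2 size factors the majority turned, with 3519 higher and 3149 lower. Among transcripts of high rank, ENSMUST00000188553 was at 27.5 and 24.9 CPM in controls and at 0 in both MM-401 libraries, at least 321-fold lower (adjusted p = 2.24e-06, edgeR). ENSMUST00000097786 was at 12.8 and 32.6 CPM in controls and 0 with MM-401, at least 278-fold lower (adjusted p = 0.0159, edgeR). ENSMUST00000127481 rose from 0 to 24.7 ± 4.22 CPM (SD, n = 2), at least 334-fold higher (adjusted p = 0.0331, edgeR). ENSMUST00000169088 rose from 0 to 9.05 ± 0.87 CPM (SD, n = 2), at least 122-fold higher (adjusted p = 0.00473, edgeR). As for the other named transcripts, these estimated counts were not whole. Of the 6681 calls, 506 had a group with at most 3 counts summed over its 2 libraries.

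The ventral-enriched set was higher with MM-401, the opposite of its direction in Smo F/F cells. Its mean log2 fold change was 0.31 (adjusted p = 2.61e-06, cameraPR, and adjusted p = 0.0387 with an estimated correlation). Its members moved both ways, with 57.7% above 0, 208 called higher and 95 called lower. The dorsal-enriched set had a mean of -0.25, with 83 called higher and 154 called lower, and did not pass the threshold (adjusted p = 0.0858, cameraPR, and adjusted p = 0.428 with an estimated correlation).

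The MM-401 count was 3528 without MM-401 replicate 1, 3755 without MM-401 control replicate 1, 3238 without MM-401 control replicate 2 and 2353 in a fit of these 4 libraries alone, and the mean of the ventral-enriched set was 0.16 without dorsal replicate 2, 0.93 over whole-count transcripts, 0.51 over abundant transcripts and 1.04 as the set of 100 smallest p. The dorsal-enriched set passed the threshold without dorsal replicate 2 (mean -0.26, adjusted p = 0.0137), ventral replicate 1 (mean -0.32, adjusted p = 0.00324) or MM-401 control replicate 1 (mean -0.23, adjusted p = 0.012), and also without a filter on low counts (adjusted p = 0.0117), over abundant transcripts (adjusted p = 0.0211) and as the set of 100 smallest p (adjusted p = 0.0225). It did not pass without ventral replicate 2, where its mean was -0.15 (adjusted p = 0.183). ENSMUST00000127481 missed the threshold without any 1 of the 4 libraries (adjusted p from 0.0643 to 0.156, edgeR) and with a replicate block (adjusted p = 0.0972), and ENSMUST00000097786 did so without either MM-401 library or control replicate 2 (adjusted p from 0.0568 to 0.0934, edgeR).

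Mll1 F/F and MM-401 are directed at the same protein, by gene deletion and by an inhibitor, for 4 and 10 days. No transcript was called in the same direction in both comparisons with edgeR, and 1 of the 3 that fell in Mll1 F/F cells rose with MM-401. Independent lists would give 0 shared rises, 0.173 shared falls and 0.141 that fell in Mll1 F/F cells and rose with MM-401. With so few Mll1 F/F calls, the absence of shared ones says little. The DESeq2 Wald test gave 42 in the same direction, for which no expected number was computed. The effects differed for 2275 transcripts when the difference itself was tested. The 1622 transcripts that MM-401 raised at least 2-fold had a mean of 0.10 in Mll1 F/F cells, with 64.1% above 0 (adjusted p = 0.000358, cameraPR, but adjusted p = 0.325 with an estimated correlation). The 2371 that it lowered had a mean of -0.019 (adjusted p = 0.943, cameraPR). The call of the raised set was lost without Mll1 control replicate 2 (adjusted p = 0.777), and its mean was 0.041 without Mll1 F/F replicate 1 and 0.19 without Mll1 control replicate 1. In Smo F/F cells the same sets had means of -0.029 and -0.032 (adjusted p = 0.943 for each, cameraPR). These depended on single libraries. The lowered set had a mean of -0.12 without Smo control replicate 1 (adjusted p = 0.000713) and 0.15 without Smo control replicate 2 (adjusted p = 0.00015), and the raised set had a mean of -0.051 without the latter (adjusted p = 0.00532). Smo F/F and Mll1 F/F shared no called transcript with edgeR, but with 3 calls in each this says little. With the DESeq2 Wald test 2 were called in the same direction in both.

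The washout comparison asked what remained 10 days after MM-401 was withdrawn. Against controls that had gone through the same washout, 326 transcripts (0.51%) differed, with 228 higher and 98 lower. Of these, 130 had also risen and 64 had also fallen with MM-401, against 10.7 and 5.65 expected of independent lists (adjusted p = 3.44e-109 and adjusted p = 5.15e-54, one-sided Fisher's exact test), while 3 and 9 were called in opposite directions. Called transcripts were more abundant than others, and washout calls permuted within abundance bins gave medians of 28 and 10 (highest 42 and 20 in 1000 permutations) in place of 10.7 and 5.65. The 194 shared calls became 1290 with the DESeq2 Wald test and 0 with a replicate block, 76 and 81 without MM-401 control replicates 1 and 2, 13 and 34 without washout replicates 1 and 2, and 5 and 15 without washout control replicates 1 and 2. The transcripts that MM-401 had raised at least 2-fold were still higher as a set, with a mean of 0.49 (0.79 over whole-count transcripts) and 77.2% above 0 (adjusted p = 6.83e-22, cameraPR, and adjusted p = 0.00977 with an estimated correlation). Those that it had lowered were still lower, with a mean of -0.50 and 78.5% below 0 (adjusted p = 4.19e-20, cameraPR, and adjusted p = 0.0138 with an estimated correlation). Both sets lay closer to control than during treatment, with medians of 0.43 and -0.44 against 1.72 and -1.81, but the treatment values are inflated because the same libraries chose the sets. With sets chosen from the libraries of 1 replicate number and measured in those of the other, the treatment medians were 1.36 and 1.46 for raised transcripts, against 0.40 and 0.34 after washout, and -1.17 and -1.56 for lowered transcripts, against -0.41 and -0.38.

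**Figure D4:**
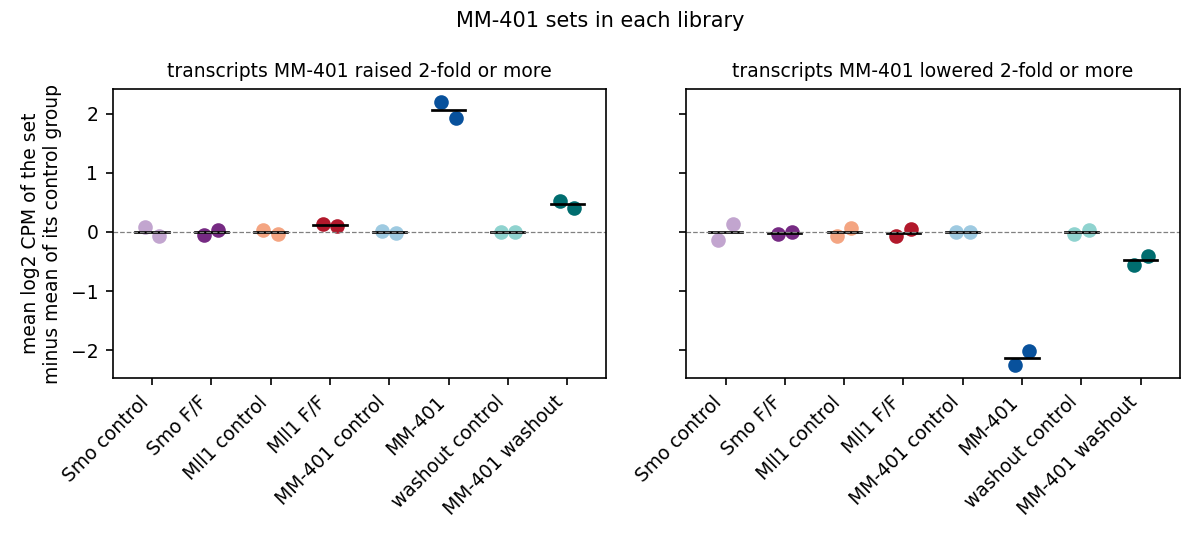
Points are single libraries and bars are means of 2, showing the mean log2 CPM of the 1622 transcripts that MM-401 raised (left) and the 2371 that it lowered (right) at least 2-fold, minus the mean of that experiment's controls. The MM-401 libraries define the sets and lie at 2.20 and 1.94 on the left, the washout libraries lie at 0.53 and 0.41 on the left and -0.55 and -0.40 on the right, and the Mll1 F/F libraries lie at 0.13 and 0.093 on the left.

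Among single transcripts after washout, ENSMUST00000159124 was at 0.753 and 0.777 CPM in controls and 0 in both washout libraries, at least 15.6-fold lower (adjusted p = 0.000547, edgeR). ENSMUST00000042509 was at 4.43 and 1.89 CPM after washout and 0 in controls, at least 66.2-fold higher (adjusted p = 0.0128, edgeR). ENSMUST00000206753 was at least 96.2-fold higher (adjusted p = 0.0485, edgeR) and ENSMUST00000109543 at least 131-fold lower (adjusted p = 0.0438, edgeR), and both missed the threshold without any 1 of the 4 libraries (adjusted p from 0.0994 to 0.26). ENSMUST00000042509 missed it without washout control replicate 1 (adjusted p = 0.115) or replicate 2 (adjusted p = 0.0733). All 4 missed it with a replicate block (adjusted p from 0.0576 to 0.161) and in a fit of these 4 libraries (adjusted p from 0.0515 to 0.0964). The estimated counts of these transcripts were not whole.

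The dorsal-enriched set was higher after washout than in its controls, with a mean of 0.21 and 60.5% above 0 (adjusted p = 0.00101, cameraPR, but adjusted p = 0.336 with an estimated correlation). The ventral-enriched set did not pass the threshold, and its mean of 0.086 and median of -0.0038 differed in sign (adjusted p = 0.285, cameraPR). Both sets differed from their response during treatment, by -0.23 for the ventral-enriched (adjusted p = 4.12e-06, cameraPR, and adjusted p = 0.0269 with an estimated correlation, but -0.11 without dorsal replicate 2, -0.74 over whole-count transcripts and -0.78 as the set of 100 smallest p) and by 0.46 for the dorsal-enriched transcripts (adjusted p = 2.33e-05, cameraPR, but adjusted p = 0.142 with an estimated correlation). The difference between washout and treatment was called for 1293 single transcripts.

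The washout count was 2746 with the DESeq2 Wald test (1625 higher and 1121 lower), 503 with limma on log2(TPM + 1), 870 over abundant transcripts alone, 0 with a replicate block and 68 in a fit of these 4 libraries, and 42, 87, 13 and 49 without washout replicate 1, washout replicate 2, washout control replicate 1 and washout control replicate 2. The dorsal-enriched set missed the threshold without washout control replicate 1 (mean 0.18, adjusted p = 0.116), over abundant transcripts (mean 0.15, adjusted p = 0.169) and over whole-count transcripts (mean 0.24, adjusted p = 0.1), and its mean was 0.12 as the set of 100 smallest p. The ventral-enriched set passed it as the set of 100 smallest p (mean 0.26, adjusted p = 6.74e-05) and without dorsal replicate 1 (mean 0.15, adjusted p = 0.0122), ventral replicate 1 (mean 0.11, adjusted p = 0.0172) or washout replicate 2 (mean 0.094, adjusted p = 0.0477). Its mean was -0.047 without ventral replicate 2, 0.034 without washout replicate 1, 0.053 without dorsal replicate 2, 0.14 without washout control replicate 1 and 0.19 over whole-count transcripts, and it did not pass in any of these.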

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

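The differences between effects were planned for single transcripts. Those of the region sets and the tests of technical accounts were added after the data were seen. The following were singled out because an effect differed between experiments when the difference itself was tested.

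The effect of MM-401 differed between washout and treatment for 1293 transcripts (57.0% upward, or 48.5% with DESeq2 size factors). Sets of MM-401-changed transcripts were also chosen from the libraries of 1 replicate number. Their treatment effect was then measured in the other libraries, with 1 library in each arm. Of those that had risen, 86.5% and 86.5% had a lower log2 fold change after washout than during treatment. Of those that had fallen, 80.4% and 85.8% had a higher one. Without single libraries of either experiment the count ran from 445 to 1459, and all but MM-401 replicate 2 moved it by more than 1.5 times: it was 701 without MM-401 replicate 1, 724 and 468 without MM-401 control replicates 1 and 2, 522 and 456 without washout replicates 1 and 2 (MM-401), and 445 and 520 without washout control replicates 1 and 2. The ventral-enriched set differed by -0.23 (-0.11 without dorsal replicate 2, -0.13 without dorsal replicate 1, -0.34 without ventral replicate 2 or MM-401 control replicate 1, -0.40 over abundant transcripts, -0.74 over whole-count transcripts and -0.78 as the set of 100 smallest p) and the dorsal-enriched set by 0.46 (adjusted p = 0.142 with an estimated correlation for the latter).

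The effect of Mll1 F/F differed from that of MM-401 for 2275 transcripts. The count was 1256 without Mll1 control replicate 1, 1474 without Mll1 F/F replicate 2, 1285 without MM-401 replicate 1, 1437 without MM-401 control replicate 1 and 1117 without MM-401 control replicate 2. The ventral-enriched set differed by -0.26 (adjusted p = 2.24e-05, cameraPR, and adjusted p = 0.0269 with an estimated correlation), or by -0.12 without Mll1 control replicate 2, -0.46 over abundant transcripts, -0.94 over whole-count transcripts and -1.02 as the set of 100 smallest p. The dorsal-enriched set differed by 0.41 (adjusted p = 0.000585, cameraPR, but adjusted p = 0.15 with an estimated correlation and adjusted p = 0.116 without Mll1 control replicate 2).

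MM-401 changed 6681 transcripts where Mll1 F/F changed 3, and each of 3 technical accounts of this met a value that it forbids. Mll1 F/F moved the 2 MM-401 sets apart by 0.0243 of the MM-401 change, with an upper 95% bound of 11.1% from the spread of same-group libraries. The MM-401 change is inflated by the choice of the sets, and with the sets chosen and measured in different libraries the shares were 4.96% and 1.06% and the bounds 13.96% and 10.33%, so that spread in the Mll1 libraries does not hide changes of the same size in the same transcripts. A wrong scale adds the same amount to every transcript and so cancels from the difference between the raised and lowered sets, but this was 2.96 and 3.66 in MM-401 and control libraries that did not choose the sets, beyond the 0.376 and 0.481 that the spread of same-group libraries allows. This bears on scaling as the sole account. With DESeq2 size factors 6668 transcripts were called, but 3519 were higher and 3149 lower, in place of 2998 and 3683. The MM-401 libraries were the shallower, at 0.627 of the mean depth of the Mll1 experiment. Smaller changes in Mll1 F/F cells or changes in other transcripts stay open, as do, untested and biological, incomplete deletion (Mll1 RNA was not checked), the shorter exposure and effects of MM-401 on other targets. The vehicle of the MM-401 controls is also uncertain (ethanol in their run names, DMSO in the treatment label). A difference of vehicle therefore stays open for every comparison with these controls.

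The transcripts that MM-401 raised and lowered were still displaced 10 days after washout, with a difference between the set means of 0.99, or 19.6% of that during treatment (30.1% and 22.6% with the sets chosen and measured in different MM-401 libraries). Of 10000 random pairs of sets matched on abundance and length, the central 95% gave differences between -0.0638 and 0.0787. Over the 142 and 168 members with whole counts the difference was 1.49 ± 0.10 (SE over transcripts). Neither the abundance and length of the members nor fractional division of reads between transcripts thus accounts for it. These tests take transcripts as independent, whereas the estimated correlation between members was 0.0596 and 0.0694. With it both sets still passed the threshold (adjusted p = 0.00977 for the raised and adjusted p = 0.0138 for the lowered set, camera). With single libraries of the washout experiment left out the difference stayed at 0.866 or above. A lasting effect of MM-401 is 1 hypothesis. Remaining compound, or growth of cells selected during treatment, are others that these libraries do not separate.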

How the results depend on the processing

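The tests restricted to whole-count or abundant transcripts and every result of the MM-401 sets and of the set differences between experiments were chosen after seeing the data, and the other alternatives were planned. With DESeq2 size factors, without a filter on low counts and with an effective length offset, every count of changed transcripts stayed within 1.5 times and every set kept its direction and call, except that the dorsal-enriched set passed the threshold with MM-401 without the filter (mean -0.25). The direction of the region sets in Smo F/F cells, of the ventral-enriched set with MM-401 and of the MM-401 sets after washout was the same in all alternatives and with each library left out. Causes were not tested unless stated.

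The counts moved with the test, the libraries in the fit and single libraries. The DESeq2 Wald test called 5143 transcripts between regions, 38 for Smo F/F, 184 for Mll1 F/F, 2746 for washout, 4014 for the washout and treatment difference and 5209 for the Mll1 and MM-401 difference. Its shared calls in the same direction were 42 (Mll1 F/F and MM-401), 1290 (MM-401 and washout) and 2 (Smo F/F and Mll1 F/F). With limma on log2(TPM + 1) the counts were 4042 between regions, 12 for Smo F/F, 15 for Mll1 F/F and 503 for washout, and on log2(TPM + 0.1) they were 3726, 8 and 12 for the first 3. An edgeR fit of only the libraries of a comparison, with 2 residual degrees of freedom in place of 10, gave 0 between regions, 0 for Smo F/F, 0 for Mll1 F/F, 2353 for MM-401, 68 for washout, 528 for the Mll1 and MM-401 difference and 22 shared by MM-401 and washout. Over whole-count transcripts alone, of which 2728 were tested, the counts were 357 between regions, 0 for Smo F/F, 0 for Mll1 F/F, 680 for MM-401, 99 for washout, and 147 and 283 for the differences of washout and of Mll1 F/F from treatment. Over abundant transcripts washout gave 870 and its difference from treatment 2098. The calls shared by MM-401 and washout were 66 over whole-count and 539 over abundant transcripts.

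It is not known whether replicate numbers pair the libraries. Deviations from the group means of same-numbered libraries correlated at 0.026 (regions), 0.024 (Smo), 0.116 (Mll1), -0.0172 (MM-401) and 0.0193 (washout), with 2 pairs each, and over abundant transcripts at 0.0908, 0.0471, 0.226, -0.022 and 0.0842 in the same order. In the Mll1 experiment replicate 1 of both groups also lay together on the first principal component. The change from replicate 1 to replicate 2 also followed transcript length alike in both (Spearman correlation 0.262 in F/F and 0.273 in controls). Pairing thus stays open there. With a replicate block, which leaves 5 residual degrees of freedom, the count was 0 for Smo F/F, 1 for Mll1 F/F, 0 for washout and 0 shared by MM-401 and washout, and no call of a set changed.

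With an estimated correlation the same means missed the threshold for the ventral-enriched (-0.18) and dorsal-enriched (0.21) sets in Smo F/F cells, the dorsal-enriched set in Mll1 F/F cells (0.16) and after washout (0.21), the MM-401-raised set in Mll1 F/F cells (0.10), and the dorsal-enriched set for the differences of washout (0.46) and of Mll1 F/F (0.41) from treatment. Whole-count members of the dorsal-enriched set missed it in Mll1 F/F cells (0.070) and after washout (0.24), with fewer transcripts tested. Over abundant transcripts that set missed it after washout (0.15) and passed it with MM-401 (-0.29). As the set of 100 smallest p, it passed with MM-401 (-0.24), and the ventral-enriched set passed after washout (0.26).

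With each library left out in turn, and the lone library of its group assumed to vary like the other groups, the counts ran from 968 to 2160 between regions, 2 to 19 for Smo F/F, 5 to 37 for Mll1 F/F, 3238 to 5302 for MM-401, 13 to 87 for washout, 445 to 1459 and 1117 to 2411 for the differences of washout and of Mll1 F/F from treatment, 0 to 3 shared by Mll1 F/F and MM-401, and 5 to 227 shared by MM-401 and washout. The means of the ventral-enriched set ran from -0.055 to 0.18 in Mll1 F/F cells and from -0.047 to 0.15 after washout. Those of the dorsal-enriched set ran from 0.077 to 0.27 in Mll1 F/F cells, from -0.33 to -0.15 with MM-401 and from 0.16 to 0.30 after washout. In Smo F/F cells the MM-401-raised set ran from -0.12 to 0.12 and passed the threshold without Smo control replicate 2 (-0.051), and the MM-401-lowered set ran from -0.12 without Smo control replicate 1, where it passed, to 0.15 without Smo control replicate 2, where it passed the threshold in the opposite direction. The MM-401-raised set ran from 0.041 to 0.19 in Mll1 F/F cells. The difference of Mll1 F/F from MM-401 for the dorsal-enriched set ran from 0.31 to 0.50 and missed the threshold without Mll1 control replicate 2 (0.38). No other set difference between experiments lost its call. Of the alternative values of the named transcripts, 55 missed the threshold and 115 did not, with no change of direction.

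Depth allowed tests of 63900 transcripts, but in simulated data most 2-fold changes were missed at this number of libraries, so the low counts for Smo F/F and Mll1 F/F do not exclude changes of that size in single transcripts. The gene lists fixed in advance and the checks of Smo and Kmt2a RNA were not run, because transcripts could not be joined to genes.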

Other observations

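The tests of neighbouring rows and of the share of whole-count transcripts called with MM-401 were written down before their results were seen. All others in this part were chosen afterwards.

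Many transcripts were called both between regions and with MM-401, and more often in the same direction. Of the transcripts that differed between regions, 895 also changed with MM-401, and 591 of these (66.0%) did so in the same direction, that is, higher in ventral cells and raised, or lower in ventral cells and lowered. The odds ratio for direction was 3.76 (adjusted p = 1.79e-21 over 2 tests, two-sided Fisher's exact test over transcripts, which are not independent). Called transcripts were more abundant than the others, so the numbers were set against 1000 permutations of the MM-401 calls within abundance bins. There were 312 (both higher, permuted median 100 and highest 132), 279 (both lower, 155 and 189), 151 (higher in ventral cells and lowered, 107 and 144) and 153 (lower in ventral cells and raised, 151 and 182), so the last did not exceed them. After washout 89 transcripts were called in both, 53 in the same direction (59.6%), with no detectable association of direction (odds ratio 1.78, adjusted p = 0.326). Across 24230 abundant transcripts, called or not, the fold changes of ventral against dorsal cells and of MM-401 showed almost no agreement (r = 0.063 and rho = -0.038). Those of Smo F/F and of ventral against dorsal cells had r = -0.15 and rho = -0.24, and those of MM-401 and of washout had r = 0.27 and rho = 0.34, where transcripts are not independent replicates.

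Smo F/F cells moved the 2 region sets apart by -0.40 although only 3 single transcripts were called. Of 10000 random pairs of sets matched on abundance and length, the central 95% lay between -0.0913 and 0.0814. The 63 and 78 set members with whole counts gave -0.38 ± 0.063 (SE over transcripts). Neither the abundance and length of the members nor fractional division of reads between transcripts thus accounts for the shift. These tests take transcripts as independent, and with an estimated correlation of 0.034 and 0.076 between members neither set passed the threshold (adjusted p = 0.055 for the ventral-enriched and adjusted p = 0.0634 for the dorsal-enriched set). Set against the spread of same-group libraries pooled over 8 groups, the difference between Smo F/F and control libraries was -3.14 standard errors, beyond the 2.31 that the t distribution allows at 5% two-sided; the same ratio was -0.766 for Mll1 F/F, 4.89 for MM-401 and -1.0 for washout, without pairing of libraries. The mean of the dorsal-enriched set was 0.21 in Smo F/F cells, 0.21 after washout and 0.16 in Mll1 F/F cells. Its rise was therefore not shown to be particular to Smo F/F cells. With an estimated correlation it also missed the threshold after washout (adjusted p = 0.336, camera) and in Mll1 F/F cells (adjusted p = 0.269, camera). The mean of the ventral-enriched set was -0.18 in Smo F/F cells, 0.055 in Mll1 F/F cells, 0.31 with MM-401 and 0.086 after washout. With single libraries left out it fell as low as -0.055 in Mll1 F/F cells and -0.047 after washout. The Smo F/F effect on the sets was not tested against the other effects. A small loss of ventral-enriched transcripts on deletion of Smo is a hypothesis, which further independent cultures with Smo RNA measured would test. It rests on 2 libraries per genotype, and any difference between those cultures other than Smo stays open.

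Transcripts changed by MM-401 clustered in the order in which the files list transcripts. Of 45051 pairs of neighbouring tested rows, 775 were called in the same direction, against a median of 302 and a highest value of 358 in 1000 permutations of the calls within abundance bins. Pairs called in opposite directions numbered 97, below the permuted median of 297. This argues against reads moving between neighbouring rows as a general account of the calls. Reads moving between transcripts that are not listed next to each other were not tested. A candidate explanation is that neighbours in the list are related transcripts with a shared response, so that 6681 calls may stand for fewer loci, and the calls formed 5906 runs of neighbouring rows. The files do not say which transcripts belong to 1 gene.

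Division of reads between transcripts may also hide changes. Of the whole-count transcripts, 19.7% were called with MM-401, against 10.5% of all tested transcripts and a median of 12.8% (highest 14.7%) in 1000 draws of other transcripts matched on abundance. Adjusted over these 2728 alone, 24.9% were called with MM-401, 328 higher and 352 lower, and 13.1% differed between regions, 146 higher and 211 lower in ventral cells. Whole-count transcripts can differ from others in ways besides the division of reads, and that was not tested.

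In the Mll1 experiment, fold changes between the replicates followed transcript length. Across 24230 abundant transcripts, the Spearman correlation of length with the change from replicate 1 to replicate 2 was 0.262 in Mll1 F/F and 0.273 in control libraries, whereas it was 0.000845 for Mll1 F/F against control. It was -0.171 between the Smo F/F replicates, -0.164 and 0.167 between the MM-401 and MM-401 control replicates, and between -0.0729 and 0.0539 for the replicates of the remaining groups. For MM-401 against control it was -0.108, for Smo F/F 0.116 and for washout 0.114.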
